A study of Mus musculus with 13 samples.

How the data were processed

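Methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq), which enriches DNA fragments carrying methylated cytosine, was analysed in 13 mouse samples. Each sample had 1 deposited peak list with the chromosome, start, end, name and score of every peak. Reads had been aligned with Bowtie 0.12.7 and peaks called with MACS 1.4.1 on the mm9 genome, per the submitters' processing notes. The settings of the caller, any control library and any pooling of libraries are not given in the sources used here. Because each list belongs to 1 sample, peaks were treated as called per sample. The score is the deposited value that the authors' caller gave to each peak. The lowest score in any list was 50, and scores served only to rank or filter peaks.

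Peak lists hold no read counts, so sequencing depth is unknown and no counting interval was computed. A region without a peak is a region where no peak was called, which does not show that methylation was absent. A longer or a higher-scoring list can come from deeper sequencing, and such a difference in depth could not be corrected. No sequencing batch or date is given in the labels used here.

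Coordinates are those of mm9, printed 1-based. The reference genome NCBIM37 is the same assembly, and every peak ended within the length of its chromosome in that reference. Genes came from GENCODE M1, which corresponds to Ensembl 65. Of these, 26048 genes annotated as protein-coding, lincRNA or processed transcript on the autosomes, X and Y were used, 22221 of them protein-coding.

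The samples were 1 embryonic stem cell (ESC) line, 8 induced pluripotent stem cell (iPSC) lines and 4 somatic populations. The iPSC lines fall into 4 groups of 2 lines by title prefix and cell of origin, and each group has a somatic population with the same prefix and origin. Lines carry separate clone numbers and were taken as replicates. The 4 somatic populations are different cell types or title prefixes with 1 sample each, so the spread among them includes those differences. Nothing in the labels says how the libraries of 1 group were prepared relative to each other, so p-values measure the spread between these samples.

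The genome was divided into bins of 1000 bp, and a bin counted as present in a sample where peaks covered at least 500 bp of it. A promoter was the region within 1000 bp either side of the annotated gene start (2001 bp), and it counted as present where peaks covered at least 1 bp. Presence in the 8 iPSC lines was compared with presence in the 4 somatic populations by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the tested features and a threshold of 0.05. Tested features were present in 3 to 9 of the 12 samples. The design described these totals as those that can reach an unadjusted p under 0.05, but a total of 6 cannot. The range was kept as written, and a run limited to the other totals was added after the data were seen.

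The smallest p this design can give is 0.00202, reached only by features present in every sample of one class and in no sample of the other. The adjusted test therefore calls either all such features or none of them, depending on how many there are. This was checked on simulated presence tables drawn from the real frequency of each feature and the share of features in each sample. With 200 planted promoters, 0 passed the adjusted threshold, although the unadjusted p was under 0.05 for 100 of 100 in one direction and 100 of 100 in the other. When 5% of the planted values were flipped, 90 and 86 had an unadjusted p under 0.05 and 0 passed after adjustment. With 400 planted promoters, 200 of 200 passed in each direction, with 14 calls that were not planted. For bins, 0 of 200 planted bins passed, and with 10000 planted bins 5000 of 5000 passed in each direction, with 146 calls that were not planted.

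Peak number, covered length and median peak width were compared by exact permutation tests over all 495 splits of the 12 samples into 8 and 4. Similarity between samples was the Jaccard index, the number of bins present in both samples divided by the number present in either. Sister lines of a group were compared with other pairs over all 105 pairings of the 8 lines. Similarity to the own source population was tested over 2520 assignments after removing line and population means. Correlations with the title prefix used exact permutation of the 8 lines. For the single ESC line, bins found in 1 pluripotent line and in no other, or missing from 1 line and found in all others, were counted for each of the 9 lines.

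A set of 11 gene lists was fixed before the data were examined. The genes matched in the annotation were 25 of 25 for pluripotency, 23 of 24 for germline, 30 of 32 for imprinted, 25 of 25 for fibroblast and mesenchymal, 17 of 18 for adipose, 25 of 25 for haematopoietic, 14 of 14 for endothelial and macrophage, 39 of 39 for Hox, 29 of 30 for developmental regulators, 15 of 15 for DNA methylation machinery and 15 of 15 for housekeeping genes. Enrichment of each list among called promoters was tested by Fisher's exact test against the tested genes. The number of list members with a peak per sample, compared by exact permutation, and the comparison with 10000 random lists matched on the number of samples with a peak were chosen after the data were seen.

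Named genes followed a rule fixed at the same time. It took the 10 fully separated promoters per direction with the largest difference in mean covered length, up to 3 called members of each list per direction, and imprinted genes present in the ESC line and in no iPSC line or the reverse. It also took the 5 longest runs of adjacent called bins per direction, and, because no bin was called, runs of fully separated bins were used in their place. Predicted genes and members of large copy families were counted and not named, and 1 gene taken by the rule is not reported here.

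Alternatives set at that time were peaks at or above the median score of all lists (107), the same number of top-scoring peaks from every list (137198), no filter on the total, the ESC line added to the iPSC lines, exclusion of X and Y, other overlaps and regions, a promoter of 500 bp either side, and each sample left out in turn. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and samtools 1.23.1.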

Results

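DNA methylation was profiled by MeDIP-seq in pluripotent and somatic mouse cells from a study of sequential reprogramming to induced pluripotent stem cells (iPSC). The pluripotent samples were the R1 embryonic stem cell (ESC) line (strain label 129, passage 20 to 22) and 8 iPSC lines (129-M2rtTA, passage 10 to 12). The iPSC lines derived from mouse embryonic fibroblasts (MEF), adipose progenitor cells (APC) or haematopoietic progenitor cells (HPC), and sample titles start with a prefix of 1, 2 or 3. Groups are named here by prefix and origin: 1-MEF-iPSC (lines 37 and 42), 2-APC-iPSC (lines 32 and 4), 2-HPC-iPSC (lines 16 and 18) and 3-APC-iPSC (lines 3 and 9). The 4 somatic populations were 1-MEF, 2-APC and 3-APC at passage 1 and 2-HPC at passage 0. The lists held 137198 to 214957 peaks, and sequencing depth is unknown because the files are peak lists.

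The iPSC lines had fewer and wider methylation peaks than the somatic populations, and the largest gap was on chromosome X. Peak numbers averaged 144045 ± 4214 (SD, n = 8 lines) in iPSC lines and 192756 ± 19257 (SD, n = 4) in somatic populations, and the ESC line had 141551. On X, iPSC lines had 941 ± 92.9 peaks and the ESC line 804, against 5435 in 1-MEF, 5476 in 2-HPC, 6098 in 3-APC and 2899 in 2-APC. On Y, the ESC line had 22 peaks and the iPSC lines 25 to 33, whereas 1-MEF had 0, 2-HPC 1, 3-APC 13 and 2-APC 30. The median deposited peak score, which can move with sequencing depth, was 99.9 ± 6.19 (93.9 to 112) in iPSC lines, 129 ± 11.5 (119 to 144) in somatic populations and 94.9 in the ESC line. Promoters with a peak numbered 4685 ± 559 in iPSC lines, 6205 ± 430 in somatic populations and 4415 in the ESC line.

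Peak number differed between iPSC lines and somatic populations in the exact permutation test (two-sided p = 0.00202, the smallest possible, and 0.00606 after Benjamini-Hochberg adjustment over 3 measures). Median peak width was 1195 ± 137 bp in iPSC lines and 973 ± 77.8 bp in somatic populations (exact permutation p = 0.0101, adjusted 0.0152), and it was 1085 bp in the ESC line. Covered length was 196 ± 24.9 Mb in iPSC lines, 209 ± 10.9 Mb in somatic populations and 173 Mb in the ESC line, a difference that did not pass (exact permutation p = 0.335). The difference, iPSC minus somatic, was -34.2 Mb with peaks at or above the median score (exact permutation p = 0.0182) and 28.7 Mb with the same number of top-scoring peaks from every list, an alternative added after the data were seen (exact permutation p = 0.0323), so these settings passed in opposite directions. The score cut of 107 lies below the median score of every somatic list and above that of most iPSC lists, so it takes out a larger share of peaks in most iPSC lines. The difference in covered length depended on the samples too. It was -13.6 Mb with all samples, -20.7 Mb without 3-APC-iPSC line 9 (exact permutation p = 0.0576) and -8.46 Mb without the 3-APC population (exact permutation p = 0.594).

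**Figure D1:**
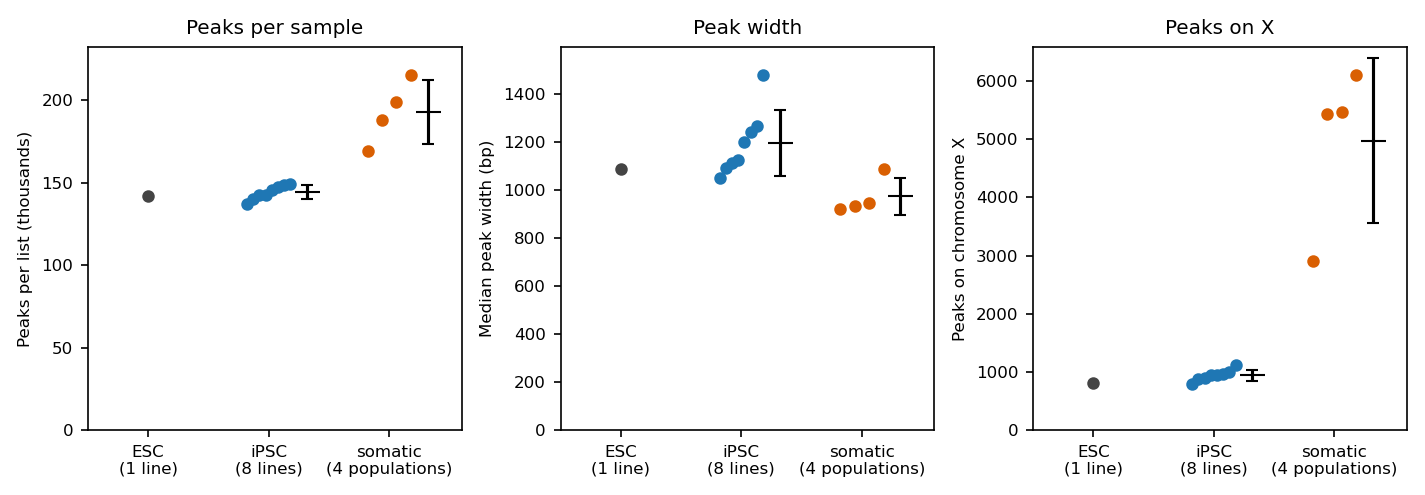
Peaks per list (axis in units of 1000), median peak width in bp and number of peaks on chromosome X for each sample, with 1 point per sample in order of value within its class; black marks show the mean and SD of the 8 iPSC lines and of the 4 somatic populations. The iPSC lines lie between 798 and 1111 peaks on X, and the somatic populations between 2899 and 6098.

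The 1 kb bins that separated the classes completely were counted, a count chosen after the data were seen, and the ESC line had most of those found in the iPSC lines. Bins present in all 8 iPSC lines and in no somatic population numbered 1256, and 77.6% of them were also present in the ESC line. In the opposite direction, 6459 bins were present in all 4 somatic populations and in no iPSC line, 91.2% of these were absent from the ESC line, and 603 lay on X. The ESC line had a peak in 173940 of 2654886 bins, so absence from it was the usual state, and the 91.2% does not show a likeness to the iPSC lines. Presence in all 8 iPSC lines is a stricter demand than presence in all 4 somatic populations, so the counts of the directions do not compare like for like. Exons without a promoter held 18.2% of the somatic bins, against 6.29% of all tested bins and 5.02% of the iPSC bins.

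The longest runs of such somatic bins covered 4 bins each and overlapped exons of Prrc2b (chromosome 2, 32067001 to 32071000), Rab6b, a Rab GTPase (chromosome 9, 103064001 to 103068000), Acvr2b, an activin receptor (chromosome 9, 119336001 to 119340000), Bahcc1 (chromosome 11, 120132001 to 120136000) and Drosha, the nuclear microRNA-processing nuclease (chromosome 15, 12840001 to 12844000). The runs at Bahcc1 and Drosha were partly present in the ESC line and the other 3 were absent. In iPSC lines the longest run had 4 bins, overlapped Mid1 and predicted genes (chromosome X, 166421001 to 166425000) and was absent from the ESC line. Runs of 3 bins overlapped Tpst2, a tyrosylprotein sulfotransferase (chromosome 5, 112738001 to 112741000), and genes known by clone names on chromosome 8 (111771001 to 111774000), and another lay between genes on chromosome 2 (173343001 to 173346000). The fifth run had 2 bins and lay 22844 bp from Ctla4 (chromosome 1, 60919001 to 60921000). These last 4 runs were present in the ESC line.

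No bin passed Fisher's exact test after Benjamini-Hochberg adjustment over 211122 bins (smallest adjusted p = 0.0553), and 6223 bins higher in iPSC lines and 18498 higher in somatic populations had an unadjusted p under 0.05. With only the totals that can reach an unadjusted p under 0.05, an alternative added after the data were seen, the adjusted p was 0.0484 over 184915 bins and all 1256 and 6459 separated bins passed. Separated iPSC bins numbered 2416 without 2-HPC, and with the same number of top-scoring peaks per list the separated counts were 2209 and 4099. Separated iPSC bins numbered 564 at the median score, 599 with wholly covered bins and 464 in merged regions, and separated somatic bins 1060 with wholly covered bins and 12528 with presence from 1 bp.

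Among gene promoters, 62 had a peak in all 8 iPSC lines and in no somatic population, and 419 had a peak in all 4 somatic populations and in no iPSC line. Of the 62, 52 also had a peak in the ESC line, and of the 419, 396 had none there. Of all promoters, 16.9% had a peak in the ESC line, so absence there was the usual state. With predicted genes and copies left out, the iPSC promoters with the largest covered length were those of Gcm2, a parathyroid transcription factor (chromosome 13, 41204357 to 41206357, 1750 ± 536 bp covered, SD, n = 8), Spaca3, a sperm acrosome protein (chromosome 11, 80670867 to 80672867, 1569 ± 202 bp), Fgf14 (chromosome 14, 125075349 to 125077349, 1514 ± 221 bp) and Adcyap1, which encodes the neuropeptide PACAP (chromosome 17, 93597762 to 93599762, 1478 ± 101 bp). Pde1a, a phosphodiesterase, Tnfrsf14, Tcf21, a mesodermal bHLH factor, and Slc10a6, a transporter of steroid sulfates, followed with means of 1450, 1438, 1324 and 1166 bp. Fv1, a retrovirus restriction gene, and Miip have overlapping promoters on chromosome 4 and cannot be separated (1289 and 1265 bp). All 10 named promoters had a peak in the ESC line, whereas some predicted genes left out here, covered over 2001 bp in iPSC lines, had none. Gcm2 was covered over 429 bp in 2-APC-iPSC line 32, and it was not called when 500 bp had to be covered or with the promoter of 500 bp either side.

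On the somatic side, 147 of the 419 promoters belonged to predicted genes or copies and were not named. Among the others the largest covered lengths were at Phf17 (chromosome 3, 41358656 to 41360656, 1934 ± 114 bp, SD, n = 4), Pnldc1, a nuclease that trims piRNAs (chromosome 17, 13101866 to 13103866, 1861 ± 90.8 bp), Prss45, a serine protease (chromosome 9, 110736092 to 110738092, 1799 ± 181 bp) and Zfp36l3 on X (51078571 to 51080571, 1735 ± 25.6 bp). Foxr1, a forkhead factor, and Zp3, an egg coat protein, had means of 1680 and 1496 bp (chromosomes 9 and 5). Tceal8, on X, had 1538 bp, and the overlapping promoters of Rnf113a1 and Ndufa1, a subunit of respiratory complex I, on X had 1592 and 1510 bp. None of these promoters had a peak in the ESC line or in an iPSC line. Of the 419 promoters, 57 lay on X.

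The 481 promoters shared an adjusted p of 0.0213 in Fisher's exact test with Benjamini-Hochberg adjustment over 5079 promoters, so 12.9% of calls were higher in iPSC lines. The directions do not compare like for like, because a call needs a peak in all 8 iPSC lines or in only 4 somatic populations. With the same number of top-scoring peaks per list, the counts were 97 and 262, 27.0% of calls were higher in iPSC lines, and Gata1, Lep, Ndufa1, Pnldc1, Rnf113a1, Tceal8 and Tcf21 were not called. With peaks at or above the median score, the counts were 18 and 425, of which 10 and 170 were among the 62 and 419, and 17 of the 31 genes taken by the naming rule were not called. Leaving out the 3-APC population raised the smallest adjusted p to 0.0511 and left 0 calls, and leaving out 2-HPC gave 95 and 491 calls. Calls are all or none, and fewer populations raise the smallest possible p, so the 0 does not show that separated promoters were lost.

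Germline and pluripotency promoters had peaks more often in somatic populations. Of 23 germline promoters, 21.8 ± 0.50 had a peak in somatic populations, 12.3 ± 1.83 in iPSC lines and 12 in the ESC line. Stk31, a testis kinase (chromosome 6, 49344603 to 49346603, 1443 ± 274 bp in somatic populations), Taf7l, a TFIID subunit of male germ cells (chromosome X, 131010029 to 131012029, 1443 ± 236 bp) and Rpl10l (chromosome 12, 67384388 to 67386388, 1109 ± 270 bp) had peaks in 4 of 4 somatic populations and 0 of 8 iPSC lines. Other germline genes had peaks in both classes: Hormad1, Brdt, Piwil2 and Tex101 in all 8 iPSC lines and all 4 somatic populations. Of 25 pluripotency promoters, 8.5 ± 2.52 had a peak in somatic populations, 2.63 ± 1.06 in iPSC lines and 1 in the ESC line.

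Dppa5a (chromosome 9, 78214984 to 78216984, 1063 ± 199 bp) and Zfp42, which encodes Rex1 (chromosome 8, 44391363 to 44393363, 912 ± 727 bp), had peaks in 4 of 4 somatic populations and 0 of 8 iPSC lines. Nanog had peaks in 4 somatic populations and 2 iPSC lines, and Dppa3 in 4 and 1, and neither was called. No peak lay at the promoters of Pou5f1, Sox2 or Klf4 in any of the 13 samples. Called members higher in somatic populations numbered 3 for the germline list and 2 for pluripotency; adjusted over the list alone they numbered 5 and 2. The number of members with a peak differed in exact permutation tests chosen after the data were seen (adjusted p = 0.0111 for each list over 11 lists, lower in all 8 iPSC lines than in any somatic population). Of all lists, 0 were enriched among called promoters (Fisher's exact test, smallest adjusted p = 0.848 over lists and directions), and 1, the germline list with 3 of 10 tested members called, had an unadjusted p under 0.05 (0.0432).

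**Figure D2:**
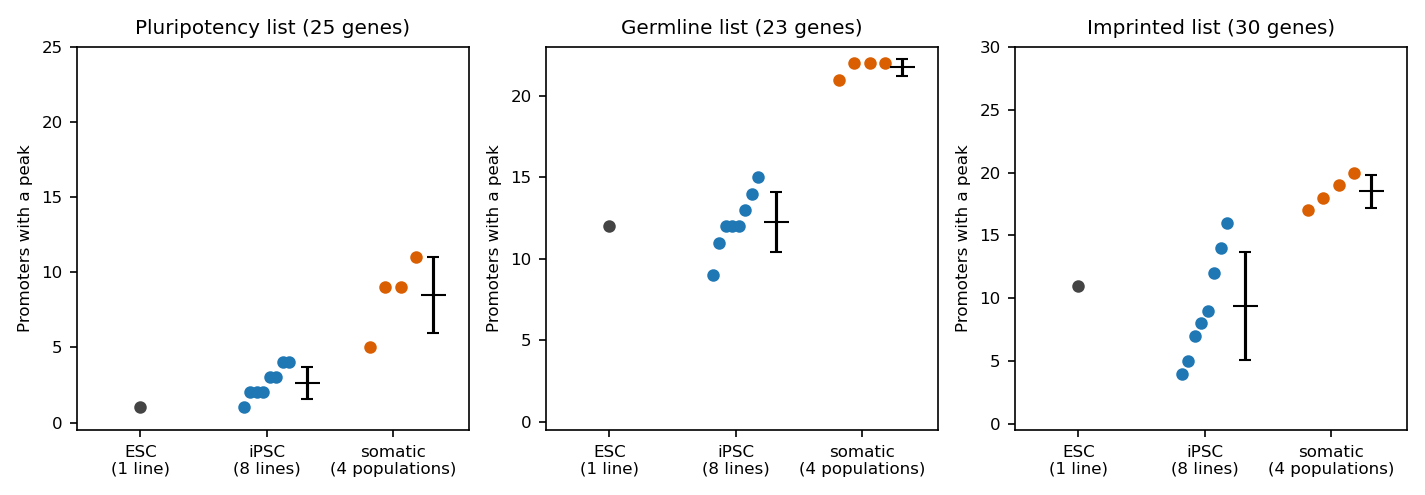
Number of promoters with a peak in the pluripotency, germline and imprinted lists for each sample, with 1 point per sample in order of value within its class; black marks show the mean and SD of the 8 iPSC lines and of the 4 somatic populations. Germline members number 21 to 22 in somatic populations and 9 to 15 in iPSC lines.

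Promoters of imprinted genes, which are expressed from the allele of a single parent, had peaks less often in iPSC lines than in somatic populations, and their number varied from line to line. Of 30 imprinted promoters, 18.5 ± 1.29 had a peak in somatic populations and 9.38 ± 4.27 in iPSC lines. For each gene only the window at its outermost annotated start was counted, so methylated regions elsewhere in a gene were missed. Some promoters, such as those of Snrpn and Grb10, had no peak in any of the 13 samples. The lines had 16 (1-MEF-iPSC line 37), 14 (3-APC-iPSC line 9), 12 (2-APC-iPSC line 32), 9 (3-APC-iPSC line 3), 8 (2-HPC-iPSC line 16), 7 (1-MEF-iPSC line 42), 5 (2-APC-iPSC line 4) and 4 (2-HPC-iPSC line 18), and the ESC line had 11. Plagl1 and Meg3 had peaks in all 13 samples. Zrsr1 (chromosome 11, 22872215 to 22874215) had a peak in the ESC line, all 4 somatic populations and lines 37, 32, 16 and 3, and no peak in lines 42, 4, 18 and 9.

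Impact (chromosome 18, 13129761 to 13131761) had a peak in the ESC line (1274 bp) and all 4 somatic populations (841 ± 501 bp) and in 0 of 8 iPSC lines, and it was the only called imprinted member. Nnat had peaks in 4 somatic populations and 1 iPSC line, Gnas in 4 and 3, and Peg10 and Sgce, which share a promoter region, in 4 and 4. Rian, a non-coding RNA of the Dlk1 and Meg3 region, had peaks in 6 iPSC lines, the ESC line and no somatic population, covering 89 to 228 bp in those iPSC lines. Adjusted over the list alone, 0 imprinted members passed Fisher's exact test (smallest adjusted p = 0.0606). Impact was not called when 500 bp of the promoter had to be covered. The number of imprinted members with a peak differed in an exact permutation test (adjusted p = 0.0222, lower in all 8 iPSC lines than in any somatic population).

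**Figure D3:**
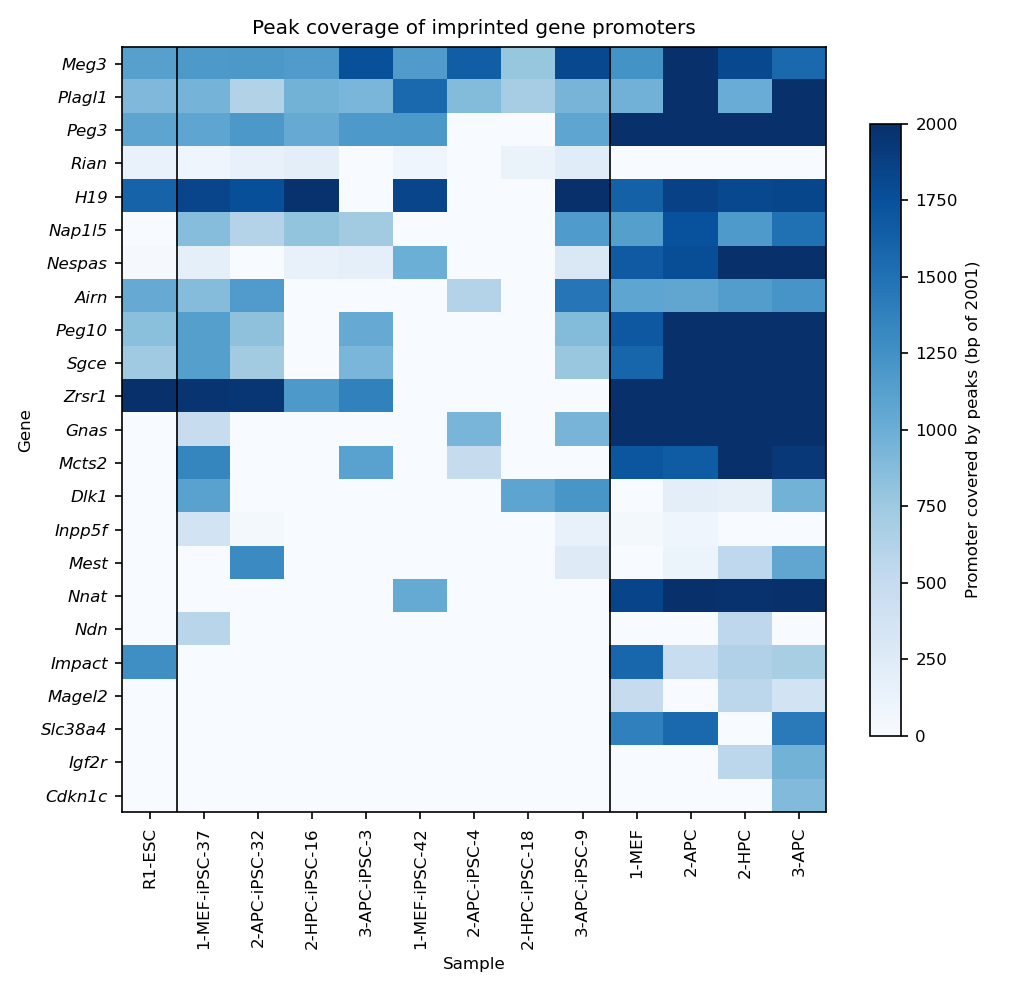
Length of each imprinted gene promoter covered by peaks, in bp of 2001, for the 13 samples in columns and the genes with at least 1 peak in rows. Zrsr1 is covered in the ESC line, 4 somatic populations and 4 of 8 iPSC lines, and Impact in no iPSC line.

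The adipose and haematopoietic lists held 1 called member each, and the Hox list 3. Lep, the leptin gene (chromosome 6, 29009220 to 29011220, 1345 ± 307 bp in somatic populations), Gata1, an erythroid factor (chromosome X, 7554197 to 7556197, 1005 ± 96.3 bp), Hoxa5 (chromosome 6, 52153586 to 52155586, 1176 ± 701 bp) and Hoxb6 (chromosome 11, 96152790 to 96154790, 446 ± 210 bp) had peaks in 4 of 4 somatic populations and 0 of 8 iPSC lines. Hoxb13 (chromosome 11, 96054630 to 96056630, 356 ± 48.7 bp in iPSC lines) had the reverse pattern. Adjusted over the list alone, 2 Hox members were higher in somatic populations and 1 in iPSC lines, 1 adipose member was higher in somatic populations, and 0 haematopoietic members passed. Hoxa5, Hoxb6 and Hoxb13 were not called when 500 bp of the promoter had to be covered.

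With all peaks and samples, members with a peak in these lists did not differ past the threshold (exact permutation, adjusted over 11 lists). Hox members numbered 6.63 ± 2.20 in iPSC lines and 10.8 ± 2.5 in somatic populations (adjusted permutation p = 0.0533), and DNA methylation machinery 2.38 ± 1.06 and 4 in each (0.0533). Adipose members numbered 4.38 ± 0.518 and 5.75 ± 1.71 (0.108), haematopoietic 6.50 ± 1.31 and 7 ± 1.41 (0.729), fibroblast and mesenchymal 3.75 ± 0.886 and 2.25 ± 0.957 (0.0889), endothelial and macrophage 6.88 ± 1.46 and 5.50 ± 1.73 (0.242), developmental regulators 4 ± 1.77 and 2.25 ± 1.26 (0.192) and housekeeping 1.88 ± 0.835 and 1.75 ± 0.957 (1). With peaks at or above the median score, a cut that takes out a larger share of peaks in most iPSC lines, the difference, iPSC minus somatic, passed for haematopoietic (-2.75 members, adjusted permutation p = 0.0222), Hox (-4.38, 0.0111) and adipose members (-2.38, 0.0370). With the same number of peaks the difference for these lists was 0.25, -2.88 and -0.875 (adjusted permutation p = 0.909, 0.137 and 0.230). In that setting it passed for fibroblast and mesenchymal members (2.25, 0.0222) and was -0.125 for DNA methylation machinery (1). With 1 sample left out it passed for fibroblast and mesenchymal members without 2-HPC-iPSC line 16 (1.75, adjusted permutation p = 0.025), for Hox members without line 16, line 18 or 1-MEF (-4.46, -4.46 and -5.04; 0.0333, 0.0417 and 0.0333), and for DNA methylation machinery without 1-MEF-iPSC line 37 or line 16 (-1.86 and -1.43; 0.0167 and 0.0444). No member of the fibroblast, endothelial, developmental, DNA methylation or housekeeping lists was called, and 0 passed when adjusted over the list alone.

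The ESC line did not stand apart from the iPSC lines in the number of bins. It had 9508 bins found in no iPSC line, rank 7 of 9 among the pluripotent lines, and lacked 4804 bins found in all 8 iPSC lines, rank 3 of 9. These counts were 5131 and 2324 at the median score and 15511 and 8159 with presence from 1 bp, where the rank by bins of its own was 5. Among promoters, 175 were found in the ESC line alone (rank 5 of 9) and 95 were missing only there (rank 4 of 9). Listed genes in these sets were Impact and Meox1, a mesodermal homeobox gene, with a peak in the ESC line and no iPSC line, and Fbxo15, with a peak in all 8 iPSC lines and none in the ESC line. Meox1 and Fbxo15 were singled out after their values were seen. With 1 ESC line the smallest p of a rank is 0.111, so no test was made, and the ESC line also differs in strain label and passage.

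Sister lines of the same origin and prefix shared little more than other pairs of iPSC lines. The Jaccard index was 0.507 between the 3-APC-iPSC lines, 0.497 between the 2-HPC-iPSC lines, 0.490 between the 2-APC-iPSC lines and 0.465 between the 1-MEF-iPSC lines. Sister pairs averaged 0.490 ± 0.0179 (SD, n = 4) and other pairs 0.483 ± 0.0264 (SD, n = 24), with a one-sided exact permutation p of 0.267. Without 1-MEF-iPSC line 37, a run added after the data were seen, the difference was 0.0227 (one-sided exact permutation p = 0.0190). The sister difference turned to -0.00334 without 2-HPC-iPSC line 16 and to -0.000917 without 3-APC-iPSC line 9. Between iPSC lines and the ESC line the index was 0.470 ± 0.0134 (n = 8), between iPSC lines and somatic populations it averaged 0.416, and among somatic populations 0.527.

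Resemblance of iPSC lines to their own source population, taken as the one with the same prefix and origin, was not detected. Of these populations, 1-MEF and 2-HPC had 0 and 1 peaks on Y, against 25 to 33 in the iPSC lines. The 1-MEF-iPSC and 2-HPC-iPSC lines thus differ on Y from the populations taken as their sources, which may not hold the cells that gave these lines. Whether the lines came from the same animals as these populations is not known. If they did not, a lack of resemblance says little about the donor cells. After line and population means were removed, the mean similarity to the own source was -0.000117 (one-sided exact permutation p = 0.512, 2520 assignments), and 2 of 8 lines were most similar to their own source. Before that correction, 7 of 8 lines had the highest index with the 2-APC population.

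**Figure D4:**
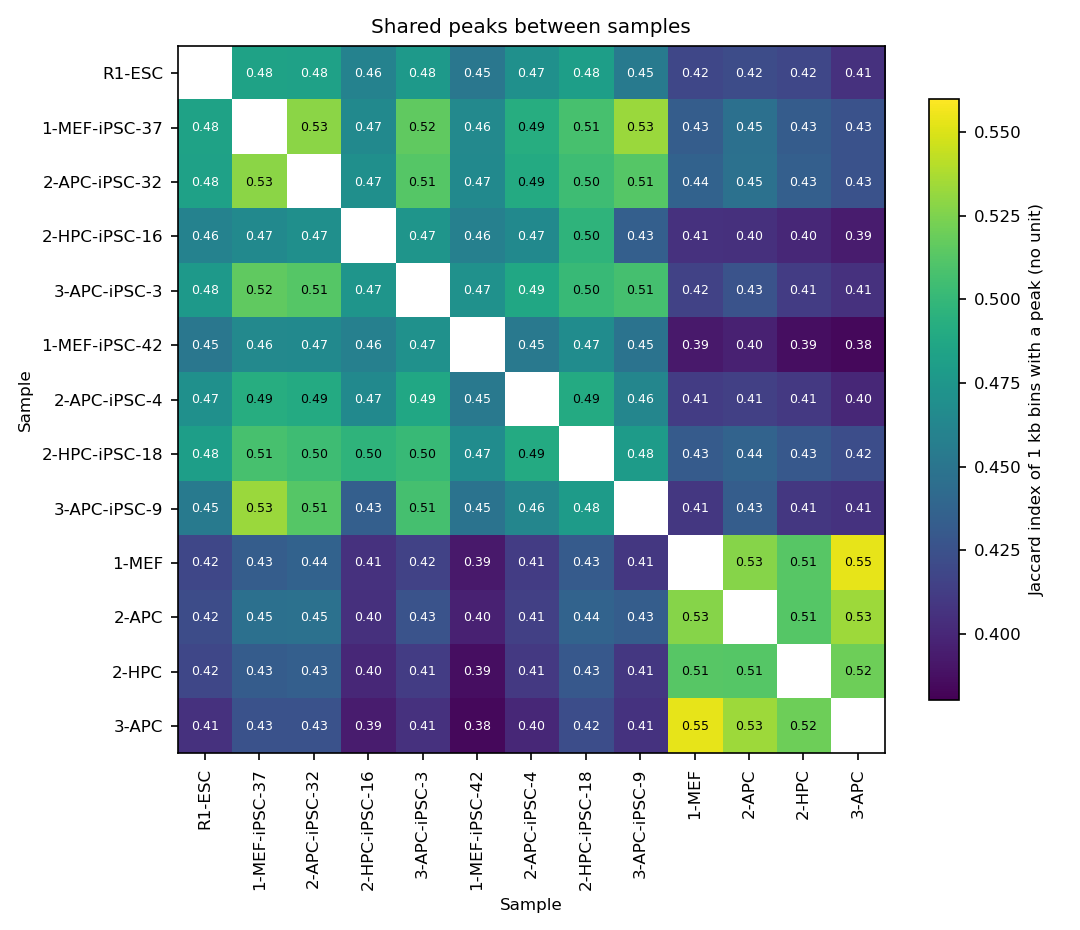
Jaccard index of 1 kb bins with a peak for every pair of the 13 samples, in rows and columns, with the value printed in each cell. Somatic populations share 0.512 to 0.553 with each other and 0.384 to 0.447 with iPSC lines.

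The contrast of title prefixes within 1 origin, 2-APC-iPSC against 3-APC-iPSC, gave 7302 bins present in both 2-APC-iPSC lines and neither 3-APC-iPSC line, and 17660 in the reverse direction. Ddx4, a germ cell RNA helicase, Tcl1, a pluripotency-associated gene, and Pdgfrb, a mesenchymal receptor, had promoter peaks in both 2-APC-iPSC lines and neither 3-APC-iPSC line. Hoxb3, Nespas, an imprinted antisense transcript, and Tfrc, the transferrin receptor gene, had the reverse pattern. With 1 line left out, the counts were 26738 and 41872 without 2-APC-iPSC line 32, 33197 and 30667 without 2-APC-iPSC line 4, 15114 and 70268 without 3-APC-iPSC line 3, and 22307 and 40689 without 3-APC-iPSC line 9, so their order turned without line 4. At the median score they were 3458 and 11202, and with presence from 1 bp 13318 and 23345. Regrouping the 4 lines into other pairs gave totals of 20199 and 25632 bins, against 24962 for the title prefixes. In every pairing the pair with 3-APC-iPSC line 9, whose list covered 245 Mb, had more bins. The counts were 17660 against 7302 for the title prefixes, and 11627 against 8572 and 19263 against 6369 for the other pairings. The excess on the side of 3-APC-iPSC can therefore not be assigned to the title prefix. The smallest p of this contrast is 0.333, and the listed genes were singled out after their values were seen.

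Across the 8 iPSC lines, title prefix was not related to peak number, covered length or similarity to the ESC line past the threshold. Peak number averaged 146955 ± 2311 (n = 2) in 1-MEF-iPSC lines, 144644 ± 4157 (n = 4) in lines of prefix 2 and 139936 ± 3872 (n = 2) in 3-APC-iPSC lines. For peak number, Pearson's r was -0.630 (exact permutation p = 0.110, adjusted 0.329 over 3 relations) and Spearman's rho -0.540 (exact permutation p = 0.210, adjusted 0.629). For covered length r was 0.300 and rho 0.231 (exact permutation p = 0.481 and 0.633, adjusted 0.721 and 0.771), and for similarity to the ESC line r was -0.0640 and rho -0.154 (exact permutation p = 0.895 and 0.771, adjusted 0.895 and 0.771). Leaving out the 2 lines of prefix 1 or the 2 of prefix 3 gave r of -0.554 and -0.333 for peak number, 0.687 and -0.508 for covered length, and -0.338 and 0.216 for similarity to the ESC line. Prefix and origin differ together except within APC, where peak number averaged 143488 for prefix 2 and 139936 for prefix 3, covered length 187 and 219 Mb, and the index with the ESC line 0.477 and 0.465.

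Somatic populations differed at single promoters of the lists, and not only in lists of other cell types. Ptprc, the leukocyte gene for CD45 (chromosome 1, 140070882 to 140072882), and Elane, the neutrophil elastase gene (chromosome 10, 79348057 to 79350057), had promoter peaks in the other 3 populations and none in 2-HPC. Col1a1, a collagen gene of mesenchymal cells (chromosome 11, 94796538 to 94798538, 1014 bp), had a promoter peak in 2-HPC and in no other somatic population. So did Hhex (chromosome 19, 37506377 to 37508377, 1147 bp), a gene of the haematopoietic list. Runx1, a haematopoietic transcription factor (chromosome 16, 92825311 to 92827311, 2001 bp), and Adipoq, the adiponectin gene (chromosome 16, 23145609 to 23147609, 802 bp), had promoter peaks in 1-MEF and in no other somatic population. Promoters with a peak in 1 population alone numbered 882 in 2-HPC, 656 in 3-APC, 446 in 2-APC and 361 in 1-MEF. These are values without a test, because each population has 1 sample, and the genes were singled out after their values were seen.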

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

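The tests on chromosome X in this part were chosen after the result was seen. Among 47 groups of values checked for a sample far from the others, 4 had one. For independent, normally distributed values chance alone gives such a sample in a share of about 0.05 of groups. Small counts with ties and measures that overlap do not meet this, so the share due to chance is not known here. The median peak width of 2-APC was 1089 bp, far from the other somatic populations (922 to 947 bp). In 2-APC, 1.71% of peaks lay on X, against 2.75 to 2.89% in the others. Germline promoters with a peak numbered 21 in 2-HPC and 22 in each other somatic population, and with the other values tied any difference is flagged. The 3-APC-iPSC line 9 had 26512 bins found in no other pluripotent line, against 8543 to 13680 in the other iPSC lines, and its list covered 245 Mb.

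Adipose promoters with a peak were more numerous in both 3-APC-iPSC lines than in their source population, by a mean of 1 gene, and less numerous in both 1-MEF-iPSC lines and both 2-HPC-iPSC lines than in theirs. These differences between groups were not tested.

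Chromosome X had 5.29 times as many peaks in somatic populations as in iPSC lines, whereas the ratio on the 19 autosomes lay between 1.26 and 1.38, which argues against a lower number of called peaks on all chromosomes as the whole cause. A candidate explanation is the number of X copies in the cells sampled, since 1-MEF and 2-HPC had 0 and 1 peaks on Y and the labels used here give no sex. In 2-APC, the 1 population with as many Y peaks as the iPSC lines, X peaks were 2.61 times those of the highest iPSC line, but a single population does not decide this, and a mixture of cells from several animals could not be examined. X peaks with a score of 100 or more, which would stay at or above the lowest score of 50 if a lower copy number took 50% of the score, numbered 3013 in 1-MEF, 1501 in 2-APC, 3157 in 2-HPC and 3728 in 3-APC, against at most 1111 X peaks in an iPSC line, but how the score moves with copies is not known from these lists. The difference between pluripotent and somatic cells, which the design names, stays open and cannot be told apart from X copies here, because no other population had as many Y peaks as the lines.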

How the results depend on the processing

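Chosen after the data were seen were the count of fully separated bins, the totals that can reach an unadjusted p under 0.05, the same number of peaks for covered length and peak width, every alternative for the number of list members with a peak, all alternatives for list enrichment except the same number of peaks, samples left out for the ESC, sister, own source, APC, title prefix and somatic results, and matching of each iPSC group to the somatic population of the same origin and title prefix. By replicate number, no paired analysis was possible because the iPSC and somatic groups share none, and line numbers are names of clones. Matched by origin and prefix, the mean difference was -48712 for peak number (lower in 4 of 4 groups), 222 bp for median width (higher in 4 of 4) and -13.6 Mb for covered length (lower in 3 of 4), and the smallest exact p of 4 differences is 0.125, so this test could not pass. In the other alternatives, peak number (difference -56573 to -41312 with samples left out) and median peak width kept their direction and side of the threshold. Own source (-0.000619 to 0.000605) and title prefix relations stayed short of the threshold in every alternative run, some with the other sign, and 0 lists were enriched in any. Covered length, iPSC minus somatic, was -34.2 Mb with peaks at or above the median score, where it passed, reversed to 28.7 Mb with the same number of peaks, where it passed too, and was -20.7 to -8.46 Mb with samples left out, without 3-APC-iPSC line 9 and without 3-APC. The cause was not tested.

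Bins called higher in iPSC lines and in somatic populations numbered 0 and 0 as reported, 564 and 7261 at the median score, 975 and 5891 with the ESC line added, 1724 and 12528 with presence from 1 bp, 464 and 6428 in merged regions, and 1256 and 6459 with attainable totals. They numbered 0 in the other alternatives. The all-or-none threshold accounts for these jumps by its construction, since the smallest adjusted p lay at 0.0553. Fully separated iPSC bins numbered 564 at the median score, 2209 with the same number of peaks, 599 with whole bins, 464 in merged regions and 1375 to 2416 with samples left out, highest without 2-HPC. Fully separated somatic bins numbered 4099 with the same number of peaks, 12528 from 1 bp and 1060 with whole bins. Called promoters higher in iPSC lines numbered 18 at the median score and 97 with the same number of peaks, and those higher in somatic populations 262 with the same number of peaks and 274 with 500 bp covered. With samples left out the ranges were 0 to 95 and 0 to 628, the 0 without 3-APC, where the smallest adjusted p was 0.0511, against 0.0395 to 0.0455 without each other somatic population. The 0 follows from the all-or-none threshold, and why the adjusted p was higher without 3-APC than without the others was not tested. Of 31 genes taken by the naming rule, 17 were not called at the median score, 8 with the same number of peaks, 5 with 500 bp covered and 5 with the shorter promoter, and 1, Impact, with the ESC line added.

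Bins in the ESC line and no iPSC line numbered 5131 at the median score and 15511 from 1 bp, and those it alone lacked 2324 and 8159. Its rank by bins of its own was 6 with the same number of peaks and 5 from 1 bp. Bins of the 2-APC-iPSC lines only numbered 3458 at the median score, 13318 from 1 bp and 15114 to 33197 with lines left out, and bins of the 3-APC-iPSC lines only 11202 at the median score and 30667 to 70268 with lines left out, where fewer lines had to share a bin or lack it, and the order of these counts turned without 2-APC-iPSC line 4. The mean index of somatic populations was 0.498 at the median score and 0.584 from 1 bp. The sister line difference was -0.00334 to 0.0227 with lines left out and passed only without 1-MEF-iPSC line 37. Among results for single genes and lists, 691 values kept their side of the threshold, 67 lost it and 10 passed it in the same direction. Where no cause is named, the cause was not tested. Depth is unknown, so no alternative could correct for it.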

Other observations

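The comparison with random lists, the test of equal peak numbers, the count of separated promoters and the correlation with covered length were chosen after the result was seen. The fibroblast and developmental lists lay on the iPSC side of random lists, and the germline list on the somatic side. Fibroblast and mesenchymal promoters had a peak in 15% of cases in iPSC lines and 9% in somatic populations, and developmental regulators in 13.8% and 7.76% (two-sided permutation of list membership, adjusted p = 0.025 for each against 10000 random lists matched on the number of samples with a peak; genes are not independent replicates). The number of members with a peak per sample did not pass in the exact permutation test for either list (adjusted p = 0.0889 and 0.192), and with peaks at or above the median score its difference went from 1.5 to 0.375 members and from 1.75 to 0.25. With the same number of peaks per list it passed for the fibroblast list (2.25 members, adjusted exact permutation p = 0.0222) and not for the developmental list (1.63, 0.230), and without 2-HPC-iPSC line 16 the fibroblast difference was 1.75 (adjusted exact permutation p = 0.025). S100a4, a calcium-binding protein gene of fibroblasts, had a promoter peak in 5 of 8 iPSC lines and 0 of 4 somatic populations, and Pdgfrb in 4 and 0. Gata4, an endoderm and heart factor, had one in 6 and 0, with a mean of 45.4 ± 44.5 bp covered in iPSC lines, and Cdx2, a trophectoderm and intestinal factor, in 5 and 0. Germline, imprinted and pluripotency lists lay on the somatic side of matched lists (adjusted permutation p = 0.0022, 0.012 and 0.025). The adipose, haematopoietic, endothelial and macrophage, Hox, DNA methylation machinery and housekeeping lists did not stand apart (adjusted permutation p = 1, 0.82, 0.29, 0.99, 0.99 and 0.38). The genes named here were singled out after their values were seen.

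Of bins specific to 1 somatic population and absent from the ESC line, 4.60 to 12.2% were found in both iPSC lines of a group. A peak was uncommon over all bins too, since each iPSC line had one in 168286 to 246792 of 2654886 bins. The share of all bins found in both lines was not computed, so low shares do not show a loss of source bins. For the own source the share was 6.82% in 1-MEF-iPSC, 6.40% in 2-APC-iPSC, 5.98% in 2-HPC-iPSC and 7.31% in 3-APC-iPSC. The 3-APC-iPSC lines held 12.2% of the 2-APC-specific bins, 9.76% of the 2-HPC-specific bins and 9.32% of the 1-MEF-specific bins. Bins specific to 3-APC had the lowest share of the 4 sources in 1-MEF-iPSC (5.54%), 2-APC-iPSC (4.60%) and 2-HPC-iPSC (4.67%) as well as in 3-APC-iPSC, whose 7.31% was the highest of the 4 groups for these bins. The 3-APC-iPSC group includes line 9, whose list covered 245 Mb, the longest of the iPSC lines. These shares were not tested.

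The excess of somatic promoter peaks was weighed against other splits of the samples and against list length. Of 100 splits of the 12 samples into 8 and 4, 1, the real one, gave 481 called promoters, and the highest other split gave 0. Because calls are all or none, fully separated promoters were also counted, and 1 of 100 splits reached 481, with 17 in the highest other split. For separated bins, 1 of 100 splits reached 7715, with 417 in the highest other. An arbitrary split of the 12 samples therefore did not give such counts. The splits give no rate of false calls, and the classes also differ in peak number and score. With the same number of peaks per list, 27.0% of calls were higher in iPSC lines. A call needs a peak in all 8 iPSC lines or in all 4 somatic populations, so an even split is not the neutral outcome where most promoters lack a peak. The test therefore cannot decide whether the longer somatic lists are the cause, and a difference in depth stays open because depth is unknown.

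The number of imprinted promoters with a peak lay below that of matched promoters in some iPSC lines. In 3 of 8 lines (1-MEF-iPSC line 42, 2-APC-iPSC line 4 and 2-HPC-iPSC line 18) the counts of 7, 5 and 4 lay below the 2.5th percentile of 10000 random lists matched on somatic peaks (medians 12, 13 and 14). This argues against fewer detected peaks at promoters in general as the whole cause in those lines. The lists were matched on somatic presence and covered length, not on score, so a loss of low-scoring peaks stays open. Peg10 and Sgce, which share a promoter region, counted as separate members. The covered length of the peak list went with the number over the 8 lines (Pearson's r = 0.772, exact permutation p = 0.0199, adjusted 0.0597 over 3 relations; Spearman's rho = 0.762, exact permutation p = 0.0368, adjusted 0.0705), but without 3-APC-iPSC line 9 and 1-MEF-iPSC line 37, the 2 farthest from the median covered length, r was 0.523 (exact permutation p = 0.290). The relation, which did not pass after adjustment, rests on those lines for its unadjusted p, but r stayed positive over the other 6, so covered length stays open. Over the 8 lines, Pearson's r with covered length was 0.734 for germline members (exact permutation p = 0.0424, adjusted 0.0636) and 0.317 for pluripotency members (exact permutation p = 0.45). Without line 9 and line 37 it was 0.159 for germline members and -0.0969 for pluripotency members. Peaks cannot tell the parental alleles apart, and no biological explanation was tested.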
